A study of Arabidopsis thaliana with 12 samples.

How the data were processed

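Gene expression was measured by paired-end RNA sequencing from 12 libraries of Arabidopsis inflorescence tips. Each genotype, Col-0, pin, pid and mp, had 3 libraries of 5 pooled meristems. Per the labels, 4 replicates were harvested and the 3 with the highest RNA integrity, all above 6, were sequenced, so replicate numbers may not stand for harvest rounds. Reads with adaptors, with a quality below 20 or from ribosomal RNA were removed by the authors. The deposited values are raw counts per annotated locus, whole numbers for 32678 loci in each library, with no normalization. The labels name TopHat2 2.0.14, HTSeq 0.9.1 and the TAIR10 genome without stating the role of each. Strand setting and treatment of reads that map to several places are not given in the sources used here, so counts of near-identical copies such as LHCB2.2 and of loci with overlapping or antisense neighbours carry that uncertainty. Totals ran from 25481808 to 34167989 counts per library.

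Symbols came from the reference annotation by locus, which matched 31912 of the 32678 loci, and no coordinates were used except the chromosome in the locus name. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci with low counts were removed by filterByExpr (minimum count 10, minimum total 15), which left 19936, and TMM factors were computed. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest with default settings) with a mean per genotype, and contrasts gave each mutant against Col-0, each mutant against each other mutant, and the mean of the 3 mutants against Col-0. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes within a comparison, and 0.05 was the threshold. Log2 fold changes are those of edgeR, with a standard error computed as the absolute value over the root of the F statistic. CPM values use the TMM library sizes and are given as mean ± SD over 3 libraries. Chloroplast and mitochondrial shares were compared between Col-0 and all mutants by an exact permutation test, since 3 against 3 libraries cannot give a two-sided p under 0.1. Principal components used log2 CPM with a prior count of 2 over the 500 most variable genes.

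Before the data were examined, 23 gene lists were written from general knowledge and fixed, together with the comparisons, the alternatives and the rule for naming genes. The lists and the 3 mutated genes held 485 symbols, of which 477 were resolved to a locus and 443 passed the count filter. The lists covered floral meristem and organ identity, early primordia and the MP pathway, Aux/IAA repressors, GH3 conjugation, auxin response factors, auxin synthesis and transport, stem cells, organ boundaries, organ polarity, flowering time, cytokinin, gibberellin, brassinosteroid, abscisic acid and dehydration, touch with wound and jasmonate, the cell cycle, photosynthetic tissue, xylem, phloem and procambium, anther with tapetum and meiosis, the epidermis, the circadian clock and flavonoids. Lists were tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 23 lists. Camera compares a list with all other genes, whereas fry tests whether its members move, on balance, one way. Members were also adjusted over the list alone, and those counts stand in parentheses; counts of members are out of those tested. Named genes were the mutated genes and 9 fixed regulators in every comparison with Col-0, up to 4 members per list with the smallest adjusted p among those past the threshold, and up to 8 genes per direction with the largest fold change among those past the threshold with an absolute log2 fold change of at least 1, a mean of at least 5 CPM and no overlap between libraries. For genes shared by all 3 mutants, up to 8 per direction with the largest smallest change were eligible. Genes named in comparisons between mutants or in the mean come from these sets, and members outside the rule are said to have been chosen after their values were seen. Where a group had no counts, a fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its 95% exact binomial counting interval.

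Sharing between mutants was compared with independent lists and with 20 simulated sets of unchanged groups measured against the same Col-0 libraries. The edgeR test was tested on simulated data with 200 changed genes, of which 62% with a log2 change of 1 and 88% with a change of 2 were recovered with 8 false calls among 158, and DESeq2 1.42.0 recovered 79% and 93% with 52 false calls among 224. Alternatives were DESeq2, RLE normalization, no count filter, a stricter filter of 1 CPM in 3 libraries, the replicate number as a block, removal of organelle genes, a fold threshold, fits of only the groups compared and fits without each library in turn. Total-count and upper-quartile normalization were added after the data had been seen. Groups were also re-split, all 10 ways for 3 against 3 libraries. For the mean and for genes shared by the 3 mutants, the real grouping and random ones made up 100 splits. A list of starvation markers, a second abscisic acid list and a list of mature seed markers were written for tests described with the closing observations. Python 3.11.15 with matplotlib 3.10.9 drew the figures. No library was left out.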

Results

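RNA was sequenced from inflorescence tips of Arabidopsis thaliana in 4 genotypes, with 3 libraries each. Col-0 is the wild type, whose inflorescence meristem forms flower primordia on its flanks. The mutants carry the alleles pin1-7, pid-9 and mpS319 and are called pin, pid and mp here; all 3 form pin-shaped inflorescences. The mutated genes encode the auxin efflux carrier PIN1, the protein kinase PINOID (PID), which acts on PIN carriers, and the auxin response factor MONOPTEROS (ARF5). The comparisons ask which transcripts differ between a flower-forming meristem and each pin-shaped meristem, which differences the 3 mutants share, and how the mutants differ from each other. Each library pooled 5 meristems, of which a tip of about 500 µm was frozen. Col-0 tips were dissected free of older buds and the pins were touched in place of dissection, so handling and the presence of young flower primordia go with genotype. The mp plants were selected on plates with 0.1 µM of the auxin analogue NAA for 10 days, whereas the other genotypes were sown on soil. P-values pool the spread of all genotypes' replicates, biological by label, though pid varied most.

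Libraries held 29094404, 28948463 and 27254114 counts in Col-0 and 26558509, 26856558 and 28147754 in pin. The pid libraries held 27053484, 34167989 and 26925972 and the mp libraries 32178299, 25481808 and 27358822. Log CPM values of libraries of 1 genotype correlated with Pearson r of 0.978 to 0.982 in Col-0, 0.979 to 0.980 in mp, 0.966 to 0.980 in pin and 0.944 to 0.962 in pid, so pid had the widest spread; these correlations run across genes, which are not independent replicates. Between Col-0 and the mutants r was 0.852 to 0.896 for pin, 0.845 to 0.874 for pid and 0.902 to 0.930 for mp. The first principal component held 45.5% of the variance of the 500 most variable genes and set Col-0, at -64.4 to -58.0, apart from mp at -1.41 to 4.18, pin at 14.9 to 26.5 and pid at 36.7 to 44.9. The second held 35.3% and set pid, at 34.1 to 53.8, apart from pin at -42.2 to -27.1. Counts from genes of the chloroplast genome made up 0.0481% ± 0.0044 (SD, n = 3) of the counts in Col-0, 0.0079% ± 0.0013 in pin, 0.0142% ± 0.0038 in pid and 0.0117% ± 0.0019 in mp. The share in Col-0 was 4.27 times the mean of the 9 mutant libraries (two-sided exact permutation test over 220 splits, p = 0.00455), and the mitochondrial share was 3.85 times as high.

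**Figure D1:**
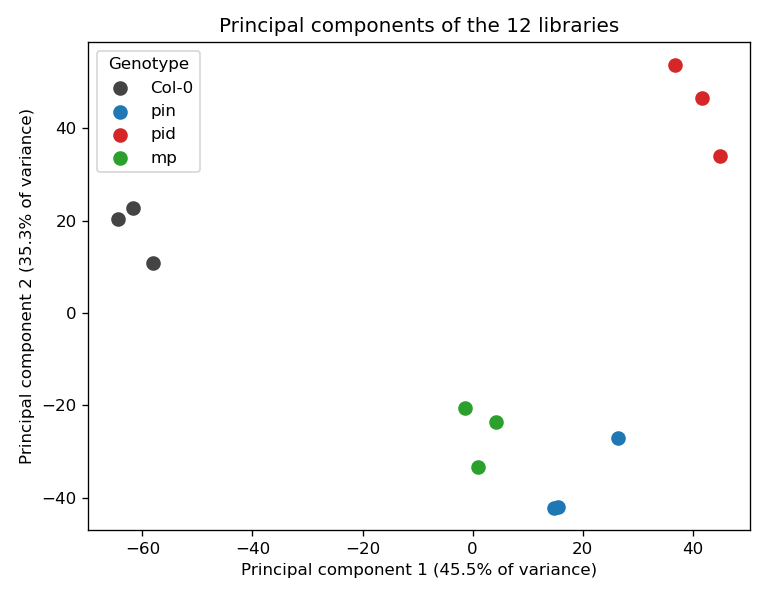
Principal components 1 and 2 of log2 CPM over the 500 most variable genes, with 1 point per library and 1 colour per genotype. The Col-0 libraries lie at -64.4 to -58.0 on the first component and all 9 mutant libraries at -1.41 or above.

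The mutated genes were examined first. PIN1 (AT1G73590) was at 122 ± 20.7 CPM (mean ± SD, n = 3 here and below) in Col-0, 54.9 ± 5.66 in pin, 86.8 ± 39.0 in pid and 98.2 ± 9.53 in mp, and passed the test against Col-0 in pin (log2 fold change -1.15, SE 0.27, adjusted p = 0.0048) but not in pid (adjusted p = 0.15) or mp (adjusted p = 0.38). It did pass for PIN1 (AT1G73590), pid vs Col-0, without pid replicate 2 (-0.91) (log2 fold change in parentheses). PID (AT2G34650) fell from 97.1 ± 18.6 to 3.81 ± 1.40 CPM (log2 fold change -4.66, SE 0.33, adjusted p = 6.9e-06) in pid. It also fell in pin, from 97.1 ± 18.6 to 55.4 ± 6.85 CPM (log2 fold change -0.81, SE 0.27, adjusted p = 0.031), a call that ended when Col-0 replicate 1 or 2 or pin replicate 2 or 3 was left out (log2 fold change -0.72, -0.77, -0.84 and -0.77). In mp, PID was at 60.3 ± 18.4 CPM (adjusted p = 0.071), and PID (AT2G34650), mp vs Col-0, passed without mp replicate 1 (-0.93), pid replicate 1 (-0.72) or pid replicate 2 (-0.72). ARF5 (AT1G19850) fell from 370.1 ± 53.7 to 23.8 ± 5.32 CPM (log2 fold change -3.96, SE 0.18, adjusted p = 1.3e-06) in mp, and to 94.2 ± 8.22 CPM in pid (log2 fold change -1.97, adjusted p = 1.9e-05). In pin it was at 267 ± 23 CPM (log2 fold change -0.47, adjusted p = 0.033), and this call ended without Col-0 replicate 3 (-0.35) or pin replicate 1 (-0.40). Transcripts of each mutated gene were thus still counted in its own mutant.

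Floral regulators and stem cell genes fixed for all 3 comparisons with Col-0 came next. AP1 (AT1G69120), a floral meristem identity gene, was at 256 ± 22.7 CPM in Col-0 and fell to 4.73 ± 3.67 in pin, 1.85 ± 1.41 in pid and 7.47 ± 3.87 in mp (adjusted p = 1.6e-04, 1.0e-04 and 5.2e-04). LFY (AT5G61850), which specifies floral fate, fell from 86.5 ± 17.6 CPM to 14.9 ± 6.41, 3.43 ± 2.21 and 11.4 ± 5.77 in the same order (adjusted p = 0.0027, 1.9e-04 and 0.0022). AG (AT4G18960), a stamen and carpel identity gene, fell from 40.7 ± 7.37 CPM to 3.63 ± 2.35 in pin (adjusted p = 7.9e-04) and 0.461 ± 0.334 in mp (adjusted p = 1.9e-04), and was at 86.6 ± 60.2 CPM in pid (adjusted p = 0.11). ESR2 (AT1G24590), an early marker of organ founder cells, fell from 4.95 ± 1.03 CPM to 1.15 ± 0.375, 0.276 ± 0.189 and 0.592 ± 0.443 in pin, pid and mp (adjusted p = 0.012, 6.1e-04 and 0.0032). AHP6 (AT1G80100), an inhibitor of cytokinin signalling, fell from 9.99 ± 0.551 CPM to 0.651 ± 0.474 in pid (adjusted p = 2.4e-04) and 1.93 ± 0.773 in mp (adjusted p = 0.0034), and was at 5.17 ± 1.45 in pin (adjusted p = 0.11). For AHP6 (AT1G80100), pin vs Col-0, the test passed without pid replicate 2 (-0.99) or pid replicate 3 (-0.95) (log2 fold change in parentheses). Among stem cell genes, WUS (AT2G17950) was at 3.85 ± 0.809 CPM in Col-0 and 0.542 ± 0.324, 0.0729 ± 0.0685 and 0.808 ± 0.381 in pin, pid and mp (adjusted p = 0.0029, 2.0e-04 and 0.012). CLV3 (AT2G27250) was at 0.874 ± 0.220 CPM in Col-0, 0.149 ± 0.163 in pin (adjusted p = 0.034), 0.211 ± 0.248 in pid (adjusted p = 0.067) and 0.372 ± 0.122 in mp (adjusted p = 0.26). For CLV3 (AT2G27250), pid vs Col-0, the test passed without pid replicate 3 (-3.61) or pin replicate 2 (-2.08). Its call in pin ended without Col-0 replicate 1 (-2.69), Col-0 replicate 2 (-2.56), Col-0 replicate 3 (-2.32), pin replicate 1 (-2.21) or pin replicate 3 (-2.11) (log2 fold change in parentheses), and for CLV3 (AT2G27250), pin vs Col-0, the value without pin replicate 2 was -3.92. STM (AT1G62360), which maintains the meristem, was at 110.3 ± 13.5 CPM in Col-0, 124 ± 15.5 in pin (adjusted p = 0.30), 159.7 ± 13.0 in pid (adjusted p = 0.0057) and 219 ± 19.5 in mp (adjusted p = 3.0e-04). TFL1 (AT5G03840), a repressor of floral fate in the inflorescence, was at 6.54 ± 1.5 CPM in Col-0, 23.5 ± 6.06 in pin (adjusted p = 5.8e-04), 8.44 ± 3.26 in pid (adjusted p = 0.32) and 16.3 ± 2.57 in mp (adjusted p = 0.0058).

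**Figure D2:**
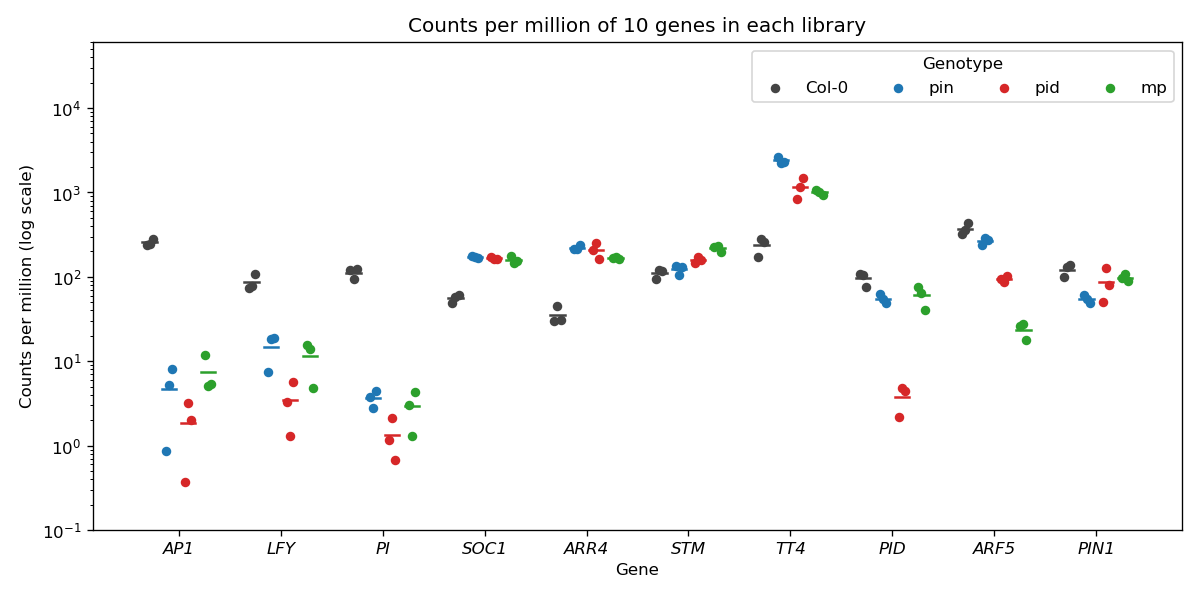
CPM of 10 genes on a log axis, with 1 point per library, a bar at the mean of the 3 libraries and 1 colour per genotype. AP1 had a mean of 256 CPM in Col-0 and at most 7.47 in a mutant, while SOC1 and ARR4 were higher in the mutants.

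In pin meristems, more genes of floral organs, organ polarity and photosynthetic tissue fell than rose against Col-0, and more genes of the vasculature, flavonoid synthesis and the cytokinin response rose than fell. Of the floral meristem and organ identity genes, 19 of 26 tested members fell and 1 rose (20 and 1 adjusted over the list alone). The floral list had a camera adjusted p of 1.0e-06 and 0.19 with an estimated correlation. The member that rose was AGL6 (AT2G45650, log2 fold change 2.16, adjusted p = 4.5e-05), named after its value was seen. PI (AT5G20240), a petal and stamen identity gene, fell from 112 ± 16.7 to 3.66 ± 0.845 CPM (log2 fold change -4.94, SE 0.42, adjusted p = 1.5e-05), and SEP3 (AT1G24260), a cofactor of the organ identity proteins, fell from 76.0 ± 16.4 to 0.564 ± 0.331 CPM (log2 fold change -7.06, SE 0.69, adjusted p = 3.0e-05). JAG (AT1G68480, log2 fold change -7.90, adjusted p = 2.7e-05), which promotes organ growth, and CRC (AT1G69180, log2 fold change -6.78, adjusted p = 4.2e-05), a carpel and nectary gene, fell. For organ polarity, 11 of 17 members fell and 1 rose (12 and 1 over the list alone). The polarity list had a camera adjusted p of 2.4e-04 and 0.26 with an estimated correlation. KAN1 (AT5G16560, log2 fold change -1.78, adjusted p = 8.6e-06), an abaxial identity gene, and TCP4 (AT3G15030, log2 fold change -4.09, adjusted p = 2.3e-05), a regulator of leaf growth, were among them. In the organ boundary list, 8 of 13 members fell and 2 rose (8 and 2 over the list alone). The boundary list had a camera adjusted p of 0.015 and 0.27 with an estimated correlation. ATH1 (AT4G32980, log2 fold change -6.49, adjusted p = 1.4e-06) and LOF1 (AT1G26780, log2 fold change -1.82, adjusted p = 9.4e-06) fell and LSH4 (AT3G23290, log2 fold change 2.61, adjusted p = 1.6e-05) rose. Of the anther, tapetum and meiosis genes, 4 of 8 members fell and 0 rose (4 and 0 over the list alone). The anther list had a camera adjusted p of 0.028 and 0.27 with an estimated correlation. The call ended without pid replicate 2 (adjusted p = 0.062). ROXY1 (AT3G02000, log2 fold change -3.20, adjusted p = 6.6e-06) and the receptor kinase gene EMS1 (AT5G07280, log2 fold change -2.08, adjusted p = 2.0e-04) fell. In the early primordium and MP pathway list, 6 of 17 members fell and 4 rose (6 and 4 over the list alone). The primordium list had a camera adjusted p of 0.10 and 0.44 with an estimated correlation. The abaxial gene YAB3 (AT4G00180) fell from 83.1 ± 13.2 to 1.12 ± 0.139 CPM (log2 fold change -6.21, SE 0.25, adjusted p = 3.9e-07), and AIL7 (AT5G65510, log2 fold change 1.56, adjusted p = 1.2e-04) and AIL5 (AT5G57390, log2 fold change 1.38, adjusted p = 7.7e-05), of the AINTEGUMENTA-like family, rose.

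Of the xylem and secondary wall genes, 15 of 19 members rose and 0 fell (15 and 0 over the list alone). Its camera adjusted p was 2.5e-05, and 0.28 with an estimated correlation. The cellulose synthase gene CESA4 (AT5G44030) rose from 1.96 ± 1.00 to 18.2 ± 11.3 CPM (log2 fold change 3.21, SE 0.50, adjusted p = 4.6e-04), and CESA7 (AT5G17420, log2 fold change 2.14, adjusted p = 2.9e-04) and the protease gene XCP2 (AT1G20850, log2 fold change 3.31, adjusted p = 5.6e-04) rose with it. For phloem and procambium, 13 of 20 members rose and 0 fell (14 and 0 over the list alone). The phloem list had a camera adjusted p of 8.6e-06 and 0.23 with an estimated correlation. These included HB15 (AT1G52150, log2 fold change 1.97, adjusted p = 3.3e-06), PXY (AT5G61480, log2 fold change 2.23, adjusted p = 9.7e-06) and WOX4 (AT1G46480, log2 fold change 2.64, adjusted p = 3.7e-05), which act in vascular patterning and in the cambium. In flavonoid and anthocyanin synthesis, 13 of 15 members rose and 0 fell (13 and 0 over the list alone). Its camera adjusted p was 1.6e-06, and 0.26 with an estimated correlation. TT4 (AT5G13930), which encodes chalcone synthase, rose from 239 ± 57.2 to 2406 ± 229 CPM (log2 fold change 3.33, SE 0.23, adjusted p = 6.0e-06), and the chalcone isomerase gene TT5 (AT3G55120, log2 fold change 2.82, adjusted p = 5.0e-06) and 4CL3 (AT1G65060, log2 fold change 3.96, adjusted p = 1.3e-05) rose as well. Of the cytokinin genes, 13 of 22 members rose and 3 fell (13 and 3 over the list alone). Its camera adjusted p was 0.0092, and 0.26 with an estimated correlation. The type-A response regulator gene ARR4 (AT1G10470) rose from 35.2 ± 8.55 to 222 ± 14.5 CPM (log2 fold change 2.66, SE 0.19, adjusted p = 6.4e-06), LOG8 (AT5G11950, log2 fold change 1.85, adjusted p = 2.3e-05) rose and LOG3 (AT2G37210, log2 fold change -4.54, adjusted p = 5.5e-05) fell. Among the Aux/IAA repressor genes, 13 of 27 members rose and 3 fell (14 and 4 over the list alone). The Aux/IAA list had a camera adjusted p of 0.02 and 0.38 with an estimated correlation. IAA19 (AT3G15540, log2 fold change 4.37, adjusted p = 2.2e-04) and IAA17 (AT1G04250, log2 fold change 3.47, adjusted p = 1.8e-04) rose. In auxin synthesis and transport, 11 of 23 members rose and 6 fell (12 and 7 over the list alone). The auxin synthesis list had a camera adjusted p of 0.16 and 0.44 with an estimated correlation. The synthesis genes TAA1 (AT1G70560, log2 fold change 2.94, adjusted p = 1.4e-06) and YUC6 (AT5G25620, log2 fold change 3.63, adjusted p = 5.4e-06) rose and YUC4 (AT5G11320, log2 fold change -3.95, adjusted p = 3.3e-05) fell. Of the flowering time and inflorescence identity genes, 9 of 19 members rose and 3 fell (9 and 3 over the list alone). The flowering time list had a camera adjusted p of 0.10 and 0.27 with an estimated correlation. The flowering promoter genes SOC1 (AT2G45660, log2 fold change 1.63, adjusted p = 3.5e-06) and AGL24 (AT4G24540, log2 fold change 2.34, adjusted p = 1.6e-05) rose and SPL5 (AT3G15270, log2 fold change -3.89, adjusted p = 7.7e-06) fell.

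Of the photosynthetic tissue genes, 22 of 24 members fell and 0 rose (22 and 0 over the list alone). The photosynthetic list had a camera adjusted p of 2.8e-09 and 0.27 with an estimated correlation. These nuclear genes, among them LHCA1 (AT3G54890, log2 fold change -1.48, adjusted p = 2.2e-05) and PSBO2 (AT3G50820, log2 fold change -2.30, adjusted p = 2.5e-05), fell beside the lower share of chloroplast genome counts (0.0079% in pin, 0.0481% in Col-0). In the epidermis and cuticle list, 15 of 20 members fell and 2 rose (15 and 2 over the list alone). The epidermis list had a camera adjusted p of 3.2e-04 and 0.27 with an estimated correlation. The epidermal identity gene PDF2 (AT4G04890, log2 fold change -1.17, adjusted p = 3.7e-05) and HTH (AT1G72970, log2 fold change -1.03, adjusted p = 4.1e-05) fell. The largest increases by the naming rule included GPT2 (AT1G61800), a plastid glucose 6-phosphate transporter gene, which rose from 0.335 ± 0.139 to 202 ± 114 CPM (log2 fold change 9.23, SE 0.71, adjusted p = 9.4e-06), and AT2G38380, which rose from 0.0893 ± 0.0483 to 156 ± 83.9 CPM (log2 fold change 10.68, SE 0.93, adjusted p = 1.6e-05). The largest decreases included ASN1 (AT3G47340), an asparagine synthetase gene induced in darkness, which fell from 1028 ± 480.2 to 0.247 ± 0.0592 CPM (log2 fold change -12.00, SE 2.03, adjusted p = 7.7e-04), and SEN1 (AT4G35770), which was at 409 ± 199 CPM in Col-0 and had 3 counts over the pin libraries, a ratio of 10931 (95% counting interval 3740.2 to 53009.8). In all, 9506 of 19936 tested genes passed the threshold, 4938 higher and 4568 lower (4435 and 5043 with total-count normalization, 4360 and 4814 with the stricter count filter), and 4082 of the 9506 had an absolute log2 fold change of at least 1. Of 23 lists 11 passed, and none of the 11 did with an estimated correlation.

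In pid meristems, more genes of floral organs, organ polarity, early primordia and the cell cycle fell than rose against Col-0, and more genes of the phloem and flavonoid synthesis rose than fell. Of the floral meristem and organ identity genes, 19 of 26 members fell and 3 rose (19 and 3 over the list alone). The floral list had a camera adjusted p of 2.3e-06 and 0.15 with an estimated correlation. PI fell from 112 ± 16.7 to 1.33 ± 0.733 CPM (log2 fold change -6.37, SE 0.46, adjusted p = 8.5e-06), the AP1 homologue CAL (AT1G26310) fell from 30.6 ± 2.55 to 0.280 ± 0.285 CPM (log2 fold change -6.76, SE 0.56, adjusted p = 1.8e-05), and the petal and stamen identity gene AP3 (AT3G54340, log2 fold change -8.66, adjusted p = 6.3e-05) fell. The 3 that rose were SHP1 (AT3G58780, log2 fold change 1.22, adjusted p = 0.0015), STK (AT4G09960, log2 fold change 3.29, adjusted p = 0.029) and AGL6 (log2 fold change 0.71, adjusted p = 0.023), which were named after their values were seen. For STK (AT4G09960), pid vs Col-0, the value was 8.14 without Col-0 replicate 1, and it no longer passed without Col-0 replicate 2 or 3 (log2 fold change 2.72 and 2.74) or without pid replicate 1 or 3 (3.24 and 2.97). AGL6 no longer passed without Col-0 replicate 1 or 2 (0.67 and 0.69) or without pid replicate 2 or 3 (0.54 and 0.62). Of the early primordium and MP pathway genes, 14 of 17 members fell and 2 rose (14 and 2 over the list alone). The primordium list had a camera adjusted p of 1.1e-05 and 0.15 with an estimated correlation. YAB3 fell from 83.1 ± 13.2 to 0.0974 ± 0.0738 CPM (log2 fold change -9.60, SE 0.33, adjusted p = 2.1e-07), and BOP2 (AT2G41370, log2 fold change -6.56, adjusted p = 4.6e-07) and CRF2 (AT4G23750, log2 fold change -1.51, adjusted p = 1.2e-05) fell, while AIL7 (log2 fold change 1.80, adjusted p = 7.3e-05) rose. For organ polarity, 12 of 17 members fell and 1 rose (13 and 1 over the list alone). The polarity list had a camera adjusted p of 2.9e-06 and 0.15 with an estimated correlation. YAB2 (AT1G08465, log2 fold change -6.07, adjusted p = 6.5e-07) and KAN1 (log2 fold change -1.35, adjusted p = 4.1e-05) were among those that fell. In the organ boundary list, 8 of 13 members fell and 2 rose (8 and 2 over the list alone). The boundary list had a camera adjusted p of 0.003 and 0.26 with an estimated correlation. ATH1 (log2 fold change -4.86, adjusted p = 3.2e-06) and HAN (AT3G50870, log2 fold change -2.72, adjusted p = 2.4e-05) fell. Of the cell cycle and DNA replication genes, 12 of 27 members fell and 0 rose (12 and 0 over the list alone). The cell cycle list had a camera adjusted p of 0.003 and 0.50 with an estimated correlation. The cyclin genes CYCA2;4 (AT1G80370, log2 fold change -2.36, adjusted p = 1.7e-05), CYCD3;3 (AT3G50070, log2 fold change -1.30, adjusted p = 8.3e-05) and CYCB1;2 (AT5G06150, log2 fold change -1.07, adjusted p = 1.9e-04) fell.

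In the epidermis and cuticle list, 12 of 20 members fell and 1 rose (13 and 2 over the list alone). The epidermis list had a camera adjusted p of 0.003 and 0.35 with an estimated correlation. ATML1 (AT4G21750, log2 fold change -1.34, adjusted p = 3.6e-04), an epidermal identity gene, and HTH (log2 fold change -0.95, adjusted p = 9.3e-05) fell. Of the brassinosteroid genes, 7 of 14 members fell and 2 rose (8 and 2 over the list alone). The brassinosteroid list had a camera adjusted p of 0.0072 and 0.15 with an estimated correlation. The synthesis genes DWF4 (AT3G50660, log2 fold change -2.36, adjusted p = 4.6e-05) and BR6OX1 (AT5G38970, log2 fold change -3.03, adjusted p = 0.0051) and the inactivation gene BAS1 (AT2G26710, log2 fold change -2.95, adjusted p = 1.6e-04) fell. Of the anther, tapetum and meiosis genes, 4 of 8 members fell and 0 rose (4 and 0 over the list alone). The anther list had a camera adjusted p of 0.0071 and 0.27 with an estimated correlation. ROXY1 (log2 fold change -4.30, adjusted p = 2.6e-06) and EMS1 (log2 fold change -3.23, adjusted p = 2.8e-05) were among those that fell. For phloem and procambium, 11 of 20 members rose and 1 fell (12 and 2 over the list alone). The phloem list had a camera adjusted p of 0.0043 and 0.30 with an estimated correlation. HB15 (log2 fold change 1.56, adjusted p = 9.6e-06) and the sucrose transporter gene SUC2 (AT1G22710, log2 fold change 2.16, adjusted p = 4.8e-04) rose. In flavonoid and anthocyanin synthesis, 9 of 15 members rose and 1 fell (10 and 1 over the list alone). The flavonoid list had a camera adjusted p of 0.0043 and 0.37 with an estimated correlation. TT4 rose from 239 ± 57.2 to 1162 ± 324 CPM (log2 fold change 2.28, SE 0.22, adjusted p = 4.0e-05). Of the GH3 auxin conjugation genes, 3 of 7 members fell and 0 rose (3 and 0 over the list alone). The GH3 list had a camera adjusted p of 0.076 and 0.37 with an estimated correlation. It passed without pid replicate 1 (0.03), adjusted p in parentheses here and below. GH3.3 (AT2G23170, log2 fold change -6.45, adjusted p = 4.2e-04) and GH3.5 (AT4G27260, log2 fold change -2.89, adjusted p = 7.4e-04) fell. Among photosynthetic tissue genes in pid, 5 of 24 members rose and 4 fell (4 and 3 over the list alone). The photosynthetic list had a camera adjusted p of 0.97 and 0.99 with an estimated correlation. Of the cytokinin genes, 13 of 22 members rose and 5 fell (14 and 5 over the list alone). The cytokinin list had a camera adjusted p of 0.071 and 0.30 with an estimated correlation. Without pid replicate 1 (0.049) or pid replicate 3 (0.028) it passed. ARR4 rose from 35.2 ± 8.55 to 208 ± 46.2 CPM (log2 fold change 2.57, SE 0.19, adjusted p = 9.6e-06), the cytokinin oxidase gene CKX7 (AT5G21482, log2 fold change 2.58, adjusted p = 6.8e-06) rose and LOG3 (log2 fold change -5.90, adjusted p = 3.0e-05) fell. For abscisic acid and dehydration, 10 of 24 members rose and 2 fell (10 and 2 over the list alone). The abscisic acid list had a camera adjusted p of 0.16 and 0.65 with an estimated correlation. Dehydration genes differed between the pid libraries: RAB18 (AT5G66400) was at 1.03, 0.509 and 3201 CPM in replicates 1, 2 and 3.

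Several loci were counted in pid and hardly at all in Col-0. AT5G15360 had 7722 counts over the pid libraries and 0 in Col-0, at least 2598-fold higher against a floor of 3 counts over the group. AT4G19240 had 4525 counts in pid and 1 in Col-0, a ratio of 4567 (95% counting interval 819 to 180419). Among the largest decreases, AT1G33430 had 1899 counts in Col-0 and 0 in pid, at least 627-fold lower, and AT5G22430 fell from 104.6 ± 22.4 to 0.107 ± 0.0905 CPM (log2 fold change -9.78, SE 1.23, adjusted p = 1.7e-04). Such intervals and floors cover counting error only, and reads were counted without molecular identifiers. In all, 8952 of 19936 genes passed the threshold, 4822 higher and 4130 lower (4183 and 4722 with total-count normalization), and 3737 had an absolute log2 fold change of at least 1. With only these 2 groups in the fit 6667 passed. Of 23 lists 10 passed, and none of the 10 did with an estimated correlation.

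In mp meristems, more genes of floral organs, organ polarity, the epidermis and photosynthetic tissue fell than rose against Col-0, and more genes of the phloem, the cytokinin response and flowering time rose than fell. Of the floral meristem and organ identity genes, 19 of 26 members fell and 3 rose (19 and 3 over the list alone). The floral list had a camera adjusted p of 1.9e-07 and 0.095 with an estimated correlation. PI fell from 112 ± 16.7 to 2.91 ± 1.54 CPM (log2 fold change -5.26, SE 0.43, adjusted p = 3.6e-05), CRC (log2 fold change -8.46, adjusted p = 6.8e-05) fell and JAG (AT1G68480) had 1633 counts in Col-0 and 3 in mp, a ratio of 523 (95% counting interval 178 to 2536). The 3 that rose were again SHP1 (log2 fold change 1.45, adjusted p = 8.8e-04), STK (log2 fold change 4.74, adjusted p = 0.0071) and AGL6 (log2 fold change 1.5, adjusted p = 7.2e-04), also named after their values were seen; without Col-0 replicate 1, the only Col-0 library with STK counts, the value for STK (AT4G09960), mp vs Col-0, was 9.59. For organ polarity, 12 of 17 members fell and 0 rose (15 and 0 over the list alone). The polarity list had a camera adjusted p of 1.4e-07 and 0.095 with an estimated correlation. YAB2 (log2 fold change -5.77, adjusted p = 1.9e-06), TCP4 (log2 fold change -3.70, adjusted p = 8.6e-05) and KAN1 (log2 fold change -1.16, adjusted p = 1.7e-04) were among those that fell. Of the early primordium and MP pathway genes, 10 of 17 members fell and 2 rose (10 and 2 over the list alone). The primordium list had a camera adjusted p of 0.0029 and 0.23 with an estimated correlation. YAB3 fell from 83.1 ± 13.2 to 2.68 ± 0.627 CPM (log2 fold change -4.95, SE 0.23, adjusted p = 1.3e-06), BOP2 (log2 fold change -3.81, adjusted p = 6.5e-06) fell, and AIL7 (log2 fold change 2.36, adjusted p = 4.2e-05) and AIL5 (log2 fold change 1.04, adjusted p = 7.9e-04) rose. In the organ boundary list, 5 of 13 members fell and 1 rose (5 and 1 over the list alone). The boundary list had a camera adjusted p of 0.037 and 0.34 with an estimated correlation. ATH1 (log2 fold change -4.40, adjusted p = 9.5e-06) fell and LSH4 (log2 fold change 2.04, adjusted p = 1.3e-04) rose. That list no longer passed without Col-0 replicate 2 (adjusted p = 0.073), mp replicate 3 (0.076), pid replicate 2 (0.081), pid replicate 3 (0.066) or pin replicate 2 (0.051). Of the anther, tapetum and meiosis genes, 4 of 8 members fell and 0 rose (4 and 0 over the list alone). The anther list had a camera adjusted p of 0.021 and 0.25 with an estimated correlation. ROXY1 (log2 fold change -3.64, adjusted p = 1.0e-05) was among those that fell.

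Of the photosynthetic tissue genes, 17 of 24 members fell and 0 rose (18 and 0 over the list alone). The photosynthetic list had a camera adjusted p of 6.6e-06 and 0.37 with an estimated correlation. LHCA4 (AT3G47470, log2 fold change -1.03, adjusted p = 6.8e-04) and PSBO2 (log2 fold change -1.37, adjusted p = 7.6e-04) were among those that fell. In the epidermis and cuticle list, 13 of 20 members fell and 1 rose (13 and 1 over the list alone). The epidermis list had a camera adjusted p of 1.7e-04 and 0.23 with an estimated correlation. HTH (log2 fold change -1.0, adjusted p = 1.3e-04) and the cuticle regulator gene MYB106 (AT3G01140, log2 fold change -1.06, adjusted p = 4.7e-04) fell. Of the brassinosteroid genes, 7 of 14 members fell and 0 rose (8 and 0 over the list alone). The brassinosteroid list had a camera adjusted p of 0.0054 and 0.095 with an estimated correlation. DWF4 (log2 fold change -1.56, adjusted p = 6.1e-04) and BAS1 (log2 fold change -1.78, adjusted p = 0.0029) fell. For abscisic acid and dehydration, 7 of 24 members fell and 0 rose (5 and 0 over the list alone). The abscisic acid list had a camera adjusted p of 0.021 and 0.40 with an estimated correlation. ABI5 (AT2G36270, log2 fold change -3.19, adjusted p = 5.5e-05) and the phosphatase gene HAI1 (AT5G59220, log2 fold change -1.96, adjusted p = 0.0036) fell, and without mp replicate 2 the list no longer passed (adjusted p = 0.075). For phloem and procambium, 11 of 20 members rose and 0 fell (12 and 0 over the list alone). The phloem list had a camera adjusted p of 6.8e-05 and 0.17 with an estimated correlation. HB15 (log2 fold change 1.34, adjusted p = 4.3e-05) and SUC2 (log2 fold change 2.30, adjusted p = 5.6e-04) rose. In flavonoid and anthocyanin synthesis, 7 of 15 members rose and 0 fell (7 and 0 over the list alone). The flavonoid list had a camera adjusted p of 0.0054 and 0.37 with an estimated correlation. TT4 rose from 239 ± 57.2 to 1001 ± 65.2 CPM (log2 fold change 2.07, SE 0.22, adjusted p = 1.3e-04). Of the cytokinin genes, 10 of 22 members rose and 4 fell (10 and 4 over the list alone). The cytokinin list had a camera adjusted p of 0.027 and 0.23 with an estimated correlation. ARR4 rose from 35.2 ± 8.55 to 168 ± 4.21 CPM (log2 fold change 2.25, SE 0.19, adjusted p = 3.9e-05), LOG8 (log2 fold change 2.34, adjusted p = 2.0e-05) rose and LOG3 (log2 fold change -5.64, adjusted p = 7.1e-05) fell. Of the flowering time and inflorescence identity genes, 10 of 19 members rose and 3 fell (10 and 3 over the list alone). The flowering time list had a camera adjusted p of 0.028 and 0.20 with an estimated correlation. SOC1 (log2 fold change 1.51, adjusted p = 1.0e-05) and AGL24 (log2 fold change 2.38, adjusted p = 4.3e-05) rose. For gibberellin, 11 of 20 members fell and 3 rose (11 and 3 over the list alone). Its camera adjusted p was 0.06, and 0.20 with an estimated correlation. Without Col-0 replicate 1 (0.044) or 3 (0.032) it passed. The DELLA gene RGL1 (AT1G66350, log2 fold change 2.05, adjusted p = 8.8e-05) rose and the inactivation gene GA2OX4 (AT1G47990, log2 fold change -4.24, adjusted p = 2.0e-04) fell. GA20OX3 (AT5G07200) had 749 counts in mp and 1 in Col-0, a ratio of 780 (counting interval 140 to 30859), and 894 in pid.

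Large increases in mp included GPT2, which rose from 0.335 ± 0.139 to 24.9 ± 9.07 CPM (log2 fold change 6.21, SE 0.67, adjusted p = 1.4e-04), and BSMT1 (AT3G11480, log2 fold change 6.41, adjusted p = 0.0088) and CYP707A4 (AT3G19270, log2 fold change 4.67, adjusted p = 4.1e-06), which encode a methyltransferase and an abscisic acid 8'-hydroxylase. Without Col-0 replicate 3 the value for BSMT1 (AT3G11480), mp vs Col-0, was 10.58. Large decreases included FOP1 (AT5G53390, log2 fold change -8.24, adjusted p = 5.5e-05) and REM22 (AT3G17010), which had 3125 counts in Col-0 and 1 in mp, a ratio of 2999.8 (95% counting interval 538 to 118524). In all, 7314 of 19936 genes passed the threshold, 3706 higher and 3608 lower (3178 and 4162 with total-count normalization), and 2744, 1235 higher and 1509 lower, had an absolute log2 fold change of at least 1. Of 23 lists 13 passed, and none of the 13 did with an estimated correlation.

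**Figure D3:**
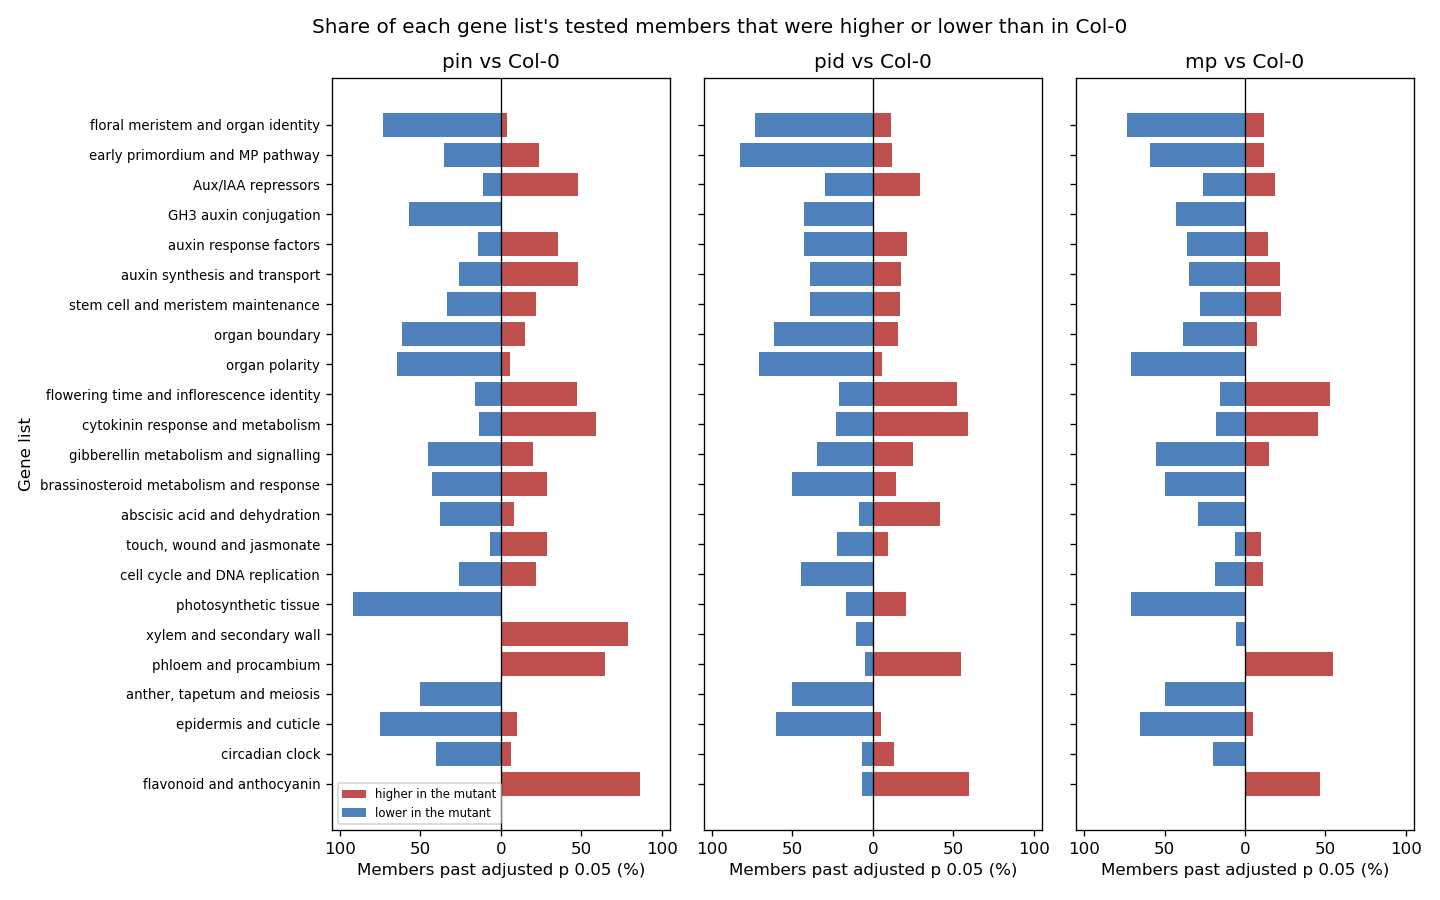
Percent of the tested members of each of the 23 gene lists that passed an adjusted p of 0.05 and were higher (right) or lower (left) than in Col-0, in 1 panel per mutant. In the floral meristem and organ identity list 19 of 26 members were lower in each mutant.

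Many differences from Col-0 were shared by the 3 mutants. Among genes lower in all 3 were the organ identity gene AP3 (AT3G54340), at 103 ± 9.42 CPM in Col-0 and 0.463 ± 0.640, 0.229 ± 0.268 and 0.937 ± 0.904 in pin, pid and mp, and SEP1 (AT5G15800), at 68.1 ± 4.30 CPM in Col-0 and 0.539 ± 0.528, 0.755 ± 0.50 and 0.526 ± 0.444. FOP1 (AT5G53390) was at 23.1 ± 2.27 CPM in Col-0 and 0.270 ± 0.236, 0.130 ± 0.0528 and 0.0756 ± 0.0718 in the mutants. Among genes higher in all 3 were GPT2, at 0.335 ± 0.139 CPM in Col-0 and 202 ± 114, 142 ± 81.2 and 24.9 ± 9.07, BSMT1 (AT3G11480), at 1.31 ± 2.15 and 111 ± 125, 299 ± 113 and 108 ± 133, and AAE12 (AT1G65890), at 0.0659 ± 0.0870 and 5.51 ± 4.48, 12.4 ± 2.2 and 6.56 ± 3.79. Past the threshold and in the same direction in all 3 were 4234 genes, 2299 higher and 1935 lower (1932 and 2313 with total-count normalization), and 1516, 756 higher and 760 lower, had an absolute log2 fold change of at least 1 in each. Independent lists of these sizes would share 222 higher and 171 lower genes. In 20 simulated sets of unchanged groups that shared 1 simulated Col-0 group the count was 0, also for every pair. That count therefore does not gauge what the shared controls add. In pairs, pin and pid shared 3048 higher and 2566 lower genes with 259 opposite (independent lists 1194 and 946), pin and mp 2982 and 2873 with 64 opposite (918 and 827), and pid and mp 2611 and 2240 with 129 opposite (896 and 747). Across genes, Pearson r of the log2 fold changes was 0.664 for pin and pid, 0.814 for pin and mp and 0.630 for pid and mp, against 0.494, 0.501 and 0.501 in the simulation. The covariance was 1.14, 1.12 and 0.866 against 0.0438, 0.0444 and 0.0444 simulated, a difference of 1.09, 1.08 and 0.822. The 3 Col-0 libraries could not be split into separate sets of at least 2, so part of the excess may come from the shared controls.

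Averaged over the 3 mutants, more floral, polarity, photosynthetic and epidermal genes fell than rose against Col-0, and more phloem and flavonoid genes rose than fell. Of the floral meristem and organ identity genes, 19 of 26 members fell and 3 rose (20 and 3 over the list alone). Camera gave the floral list an adjusted p of 9.3e-09 and 0.072 with an estimated correlation. For organ polarity, 12 of 17 members fell and 0 rose (12 and 0 over the list alone). Camera gave the polarity list an adjusted p of 8.8e-07 and 0.16 with an estimated correlation. For early primordia and the MP pathway 12 of 17 members fell and 2 rose (12 and 2 over the list alone). Camera gave the primordium list an adjusted p of 4.5e-04 and 0.22 with an estimated correlation. In the organ boundary list 8 of 13 members fell and 1 rose (9 and 1 over the list alone). Camera gave the boundary list an adjusted p of 0.0051 and 0.22 with an estimated correlation. In the anther, tapetum and meiosis list 4 of 8 members fell and 0 rose (4 and 0 over the list alone). Camera gave the anther list an adjusted p of 0.0092 and 0.22 with an estimated correlation. Of the photosynthetic tissue genes 18 of 24 members fell and 2 rose (19 and 2 over the list alone). Camera gave the photosynthetic list an adjusted p of 8.9e-05 and 0.42 with an estimated correlation. Of the epidermis and cuticle genes 14 of 20 members fell and 2 rose (14 and 2 over the list alone). Camera gave the epidermis list an adjusted p of 3.4e-04 and 0.22 with an estimated correlation. Of the brassinosteroid genes 9 of 14 members fell and 0 rose (9 and 0 over the list alone). Camera gave the brassinosteroid list an adjusted p of 0.021 and 0.16 with an estimated correlation. For phloem and procambium 14 of 20 members rose and 0 fell (14 and 0 over the list alone). Camera gave the phloem list an adjusted p of 7.3e-05 and 0.16 with an estimated correlation. For flavonoids 13 of 15 members rose and 1 fell (13 and 1 over the list alone). Camera gave the flavonoid list an adjusted p of 3.0e-04 and 0.22 with an estimated correlation. For cytokinin 13 of 22 members rose and 4 fell (13 and 5 over the list alone). Camera gave the cytokinin list an adjusted p of 0.048 and 0.22 with an estimated correlation. Of the GH3 genes, 3 of 7 members fell and 0 rose (3 and 0 over the list alone). Camera gave the GH3 list an adjusted p of 0.047 and 0.30 with an estimated correlation. The cytokinin, GH3 and brassinosteroid lists lay near the threshold, given here as adjusted p in parentheses. The cytokinin list no longer passed without Col-0 replicate 1 (0.061), Col-0 replicate 3 (0.059) or pin replicate 1 (0.05). The GH3 list no longer passed without Col-0 replicate 2 (0.054), mp replicate 3 (0.053), pid replicate 2 (0.10), pid replicate 3 (0.063), pin replicate 1 (0.054) or pin replicate 2 (0.06), and the brassinosteroid list without Col-0 replicate 3 (0.058).

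Lists that did not pass on average held members that went both ways. Of the stem cell and meristem maintenance genes, 9 of 18 members fell and 5 rose (9 and 5 over the list alone). Camera gave the stem cell list an adjusted p of 0.47 and 0.82 with an estimated correlation. For the auxin response factor genes 4 of 14 members rose and 4 fell (5 and 5 over the list alone). Camera gave the response factor list an adjusted p of 0.93 and 0.97 with an estimated correlation. For touch, wound and jasmonate 5 of 31 members rose and 4 fell (3 and 2 over the list alone). Camera gave the touch list an adjusted p of 0.85 and 0.97 with an estimated correlation. For the circadian clock 4 of 15 members fell and 1 rose (3 and 1 over the list alone). Camera gave the clock list an adjusted p of 0.44 and 0.85 with an estimated correlation. Of the cell cycle genes 8 of 27 members fell and 3 rose (8 and 3 over the list alone). Camera gave the cell cycle list an adjusted p of 0.42 and 0.85 with an estimated correlation. Of the gibberellin genes 10 of 20 members fell and 4 rose (12 and 5 over the list alone). Camera gave the gibberellin list an adjusted p of 0.089 and 0.22 with an estimated correlation. Of the flowering time genes 9 of 19 members rose and 4 fell (11 and 4 over the list alone). Camera gave the flowering time list an adjusted p of 0.072 and 0.22 with an estimated correlation. The flowering time list passed without mp replicate 1 (0.045), mp replicate 2 (0.05), mp replicate 3 (0.043) or pin replicate 3 (0.046). For xylem 3 of 19 members rose and 1 fell (0 and 0 over the list alone). Camera gave the xylem list an adjusted p of 0.42 and 0.85 with an estimated correlation. For abscisic acid 6 of 24 members fell and 3 rose (6 and 2 over the list alone). Camera gave the abscisic acid list an adjusted p of 0.37 and 0.82 with an estimated correlation. For auxin synthesis and transport 10 of 23 members fell and 7 rose (10 and 7 over the list alone). Camera gave the auxin synthesis list an adjusted p of 0.48 and 0.82 with an estimated correlation. For Aux/IAA repressors 11 of 27 members rose and 5 fell (11 and 6 over the list alone). Camera gave the Aux/IAA list an adjusted p of 0.53 and 0.85 with an estimated correlation. In all, 9816 of 19936 genes passed, 4936 higher and 4880 lower (4300 and 5593 with total-count normalization), and 3387, 1687 higher and 1700 lower, had an absolute log2 fold change of at least 1; 12 of 23 lists passed, and none did with an estimated correlation.

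In pid against pin, more photosynthetic and dehydration genes rose than fell, and more xylem, early primordium and auxin genes fell than rose. Of the photosynthetic tissue genes, 24 of 24 members rose and 0 fell (24 and 0 over the list alone). Camera gave the photosynthetic list an adjusted p of 8.9e-16 and 0.21 with an estimated correlation. Of the xylem and secondary wall genes, 15 of 19 members fell and 0 rose (16 and 0 over the list alone). Camera gave the xylem list an adjusted p of 3.6e-08 and 0.21 with an estimated correlation. CESA4 (log2 fold change -3.12, adjusted p = 0.0013) and CESA7 (log2 fold change -1.72, adjusted p = 0.0021) fell. For early primordia and the MP pathway, 14 of 17 members fell and 0 rose (14 and 0 over the list alone). Camera gave the primordium list an adjusted p of 1.5e-07 and 0.14 with an estimated correlation. CRF2 (log2 fold change -0.89, adjusted p = 5.0e-04) and YAB3 (log2 fold change -3.39, adjusted p = 2.7e-04) fell. In auxin synthesis and transport, 14 of 23 members fell and 3 rose (15 and 3 over the list alone). Camera gave the auxin synthesis list an adjusted p of 6.8e-06 and 0.14 with an estimated correlation. Among Aux/IAA repressors 14 of 27 members fell and 1 rose (15 and 1 over the list alone). Camera gave the Aux/IAA list an adjusted p of 7.5e-05 and 0.21 with an estimated correlation. Among auxin response factors 7 of 14 members fell and 0 rose (7 and 0 over the list alone). Camera gave the response factor list an adjusted p of 0.0031 and 0.37 with an estimated correlation. IAA19 (AT3G15540) fell from 30.4 ± 6.53 to 0.991 ± 0.294 CPM (log2 fold change -4.92, SE 0.62, adjusted p = 4.1e-04), and ARF5 fell from 267 ± 23 to 94.2 ± 8.22 CPM (log2 fold change -1.5, SE 0.17, adjusted p = 2.3e-04). In the flavonoid list 8 of 15 members fell and 0 rose (9 and 0 over the list alone). Camera gave the flavonoid list an adjusted p of 4.4e-06 and 0.21 with an estimated correlation. In the phloem and procambium list 9 of 20 members fell and 1 rose (11 and 2 over the list alone). Camera gave the phloem list an adjusted p of 0.0022 and 0.21 with an estimated correlation. Of the cell cycle genes 11 of 27 members fell and 0 rose (18 and 0 over the list alone). Camera gave the cell cycle list an adjusted p of 6.5e-06 and 0.38 with an estimated correlation. Of the stem cell genes 8 of 18 members fell and 2 rose (10 and 2 over the list alone). Camera gave the stem cell list an adjusted p of 0.014 and 0.21 with an estimated correlation. For abscisic acid and dehydration 13 of 24 members rose and 0 fell (16 and 0 over the list alone). Camera gave the abscisic acid list an adjusted p of 5.5e-05 and 0.21 with an estimated correlation. Without pid replicate 3, which stood apart for RAB18, the list abscisic acid and dehydration, pid vs pin, had adjusted p = 9.2e-05. For the circadian clock 7 of 15 members rose and 0 fell (7 and 0 over the list alone). Camera gave the clock list an adjusted p of 0.014 and 0.67 with an estimated correlation. The clock call ended without pid replicate 3 (adjusted p = 0.11). CAL fell from 52.7 ± 7.28 to 0.280 ± 0.285 CPM (log2 fold change -7.55, SE 0.57, adjusted p = 3.5e-05) and YAB2 fell from 19.2 ± 5.08 to 0.513 ± 0.185 CPM (log2 fold change -5.23, SE 0.29, adjusted p = 4.9e-06). RAB18 was at 0.122 ± 0.179 CPM in pin and 1068 ± 1848 in pid (log2 fold change 13.03, adjusted p = 0.015), and no longer passed without pid replicate 3 (2.60), pin replicate 1 (12.47) or pin replicate 2 (12.62). In all, 5822 genes passed, 3042 higher and 2780 lower, 2341 of them with an absolute log2 fold change of at least 1; without pin replicate 2 there were 3648, and with only these 2 groups in the fit 3217. Of 23 lists 12 passed, none with an estimated correlation.

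In mp against pin, more xylem, flavonoid and Aux/IAA genes fell than rose, and more photosynthetic genes rose than fell. Of the xylem and secondary wall genes, 15 of 19 members fell and 0 rose (16 and 0 over the list alone). Camera gave the xylem list an adjusted p of 8.7e-14 and 0.18 with an estimated correlation. CESA4 (log2 fold change -4.33, adjusted p = 0.0012), CESA7 (log2 fold change -2.12, adjusted p = 0.0023) and the protease gene XCP1 (AT4G35350, log2 fold change -5.11, adjusted p = 0.0058) fell. In flavonoid synthesis, 8 of 15 members fell and 0 rose (14 and 0 over the list alone). Camera gave the flavonoid list an adjusted p of 9.8e-11 and 0.18 with an estimated correlation. TT4 fell from 2406 ± 229 to 1001 ± 65.2 CPM (log2 fold change -1.27, SE 0.21, adjusted p = 0.0046). Among Aux/IAA repressors, 13 of 27 members fell and 1 rose (15 and 1 over the list alone). Camera gave the Aux/IAA list an adjusted p of 1.4e-07 and 0.18 with an estimated correlation. IAA19 fell from 30.4 ± 6.53 to 0.886 ± 0.666 CPM (log2 fold change -5.08, SE 0.63, adjusted p = 0.0012). In auxin synthesis and transport 11 of 23 members fell and 3 rose (15 and 4 over the list alone). Camera gave the auxin synthesis list an adjusted p of 8.5e-05 and 0.18 with an estimated correlation. In phloem and procambium 8 of 20 members fell and 1 rose (9 and 2 over the list alone). Camera gave the phloem list an adjusted p of 0.0037 and 0.32 with an estimated correlation. Of the photosynthetic tissue genes 11 of 24 members rose and 0 fell (16 and 0 over the list alone). Camera gave the photosynthetic list an adjusted p of 1.3e-08 and 0.36 with an estimated correlation. For the organ boundary list, 4 of 13 members rose and 1 fell (5 and 2 over the list alone). Camera gave the boundary list an adjusted p of 0.024 and 0.36 with an estimated correlation. UMAMIT14 (AT2G39510), an amino acid transporter gene, rose from 0.285 ± 0.206 to 24.7 ± 4.92 CPM (log2 fold change 6.42, SE 0.64, adjusted p = 4.8e-04), DIN10 (AT5G20250, log2 fold change 4.19, adjusted p = 0.0086) rose, and YAB2 fell from 19.2 ± 5.08 to 0.627 ± 0.113 CPM (log2 fold change -4.93, SE 0.28, adjusted p = 1.6e-05). In all, 2303 genes passed, 998 higher and 1305 lower, 1087 with an absolute log2 fold change of at least 1. The count fell to 1179, 1295 and 1326 without mp replicates 1, 2 and 3 and to 1286 and 1344 without pin replicates 2 and 3; of 23 lists 7 passed, none with an estimated correlation.

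In mp against pid, more photosynthetic and dehydration genes fell than rose, and more cell cycle, early primordium and stem cell genes rose than fell. Of the photosynthetic tissue genes 15 of 24 members fell and 0 rose (16 and 0 over the list alone). Camera gave the photosynthetic list an adjusted p of 1.4e-07 and 0.63 with an estimated correlation. For abscisic acid and dehydration, 16 of 24 members fell and 0 rose (18 and 0 over the list alone). Camera gave the abscisic acid list an adjusted p of 6.5e-06 and 0.38 with an estimated correlation. The pid libraries differed here, with RAB18 at 1.03, 0.509 and 3201 CPM in replicates 1, 2 and 3, and without pid replicate 3 the list abscisic acid and dehydration, mp vs pid, had adjusted p = 3.7e-05. Of the cell cycle genes, 8 of 27 members rose and 0 fell (14 and 0 over the list alone). Camera gave the cell cycle list an adjusted p of 8.7e-06 and 0.65 with an estimated correlation. The mitotic cyclin gene CYCB1;2 rose from 56.5 ± 4.83 to 88.8 ± 10.8 CPM (log2 fold change 0.65, SE 0.13, adjusted p = 0.0078). Of the early primordium and MP pathway genes, 10 of 17 members rose and 0 fell (11 and 0 over the list alone). Camera gave the primordium list an adjusted p of 2.7e-05 and 0.38 with an estimated correlation. BOP2 (log2 fold change 2.74, adjusted p = 2.6e-04) and CRF2 (log2 fold change 0.76, adjusted p = 0.002) rose. Of the stem cell and meristem maintenance genes, 9 of 18 members rose and 0 fell (9 and 0 over the list alone). Camera gave the stem cell list an adjusted p of 0.0022 and 0.38 with an estimated correlation. In the organ boundary list 5 of 13 members rose and 1 fell (6 and 1 over the list alone). Camera gave the boundary list an adjusted p of 0.0055 and 0.38 with an estimated correlation. PID rose from 3.81 ± 1.40 to 60.3 ± 18.4 CPM (log2 fold change 3.98, SE 0.32, adjusted p = 9.7e-05) and ARF5 fell from 94.2 ± 8.22 to 23.8 ± 5.32 CPM (log2 fold change -1.98, SE 0.17, adjusted p = 1.5e-04). ERF5 (AT5G47230) and ERF6 (AT4G17490), transcription factor genes of the touch, wound and jasmonate list, rose from 6.15 ± 4.27 to 67.8 ± 48.5 CPM (log2 fold change 3.45, SE 0.79, adjusted p = 0.012) and from 6.88 ± 5.24 to 70.5 ± 34.9 CPM (log2 fold change 3.35, SE 0.80, adjusted p = 0.015). Of that whole list, 6 of 31 members rose and 0 fell (6 and 0 over the list alone). Camera gave the touch list an adjusted p of 0.16 and 0.80 with an estimated correlation. It passed without mp replicate 2 (0.014) or mp replicate 3 (0.027). In all, 4415 genes passed, 1955 higher and 2460 lower, 1934 with an absolute log2 fold change of at least 1. The count fell to 2597 and 2146 without mp replicates 1 and 2 and to 2285 with only these 2 groups in the fit; of 23 lists 6 passed, none with an estimated correlation.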

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

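These differences between mutants came from genes eligible for naming, and none was singled out before the data were examined. Genes were picked here when a direct test between mutants passed while the genes moved in opposite directions from Col-0. Of 226 genes eligible for naming 8 did so, and only the 3 that the text names are described. UMAMIT14 (AT2G39510), an amino acid transporter gene, was -4.30 on the log2 scale in pin against Col-0, 1.3 in pid and 2.12 in mp, which made 5.6 for pid against pin (adjusted p = 2.6e-04) and 6.42 for mp against pin (adjusted p = 4.8e-04). Its change in pid against Col-0 no longer passed without Col-0 replicate 1 or 3 (1.35, 1.01), mp replicate 1, 2 or 3 (1.28 each), pid replicate 1 or 3 (1.25, 0.85) or pin replicate 2 (1.28). ABCB15 (AT3G28345), of the ABC transporter family, was 2.43 in pin, -2.05 in pid and -2.98 in mp, which made -4.48 for pid against pin (adjusted p = 7.7e-04) and -5.40 for mp against pin (adjusted p = 0.0013). For ABCB15 the call in pid against Col-0 ended without pid replicate 1 (-1.98) or pid replicate 3 (-1.74). PSBO2 (AT3G50820), a photosystem II gene, was -2.30 in pin, 0.55 in pid and -1.37 in mp, which made 2.85 for pid against pin (adjusted p = 3.9e-05) and -1.92 for mp against pid (adjusted p = 4.6e-04). For PSBO2 the call in pid against Col-0 ended without any 1 of several libraries. These were Col-0 replicate 1, 2 or 3 (0.60, 0.41, 0.65), mp replicate 1 (0.54), pid replicate 1, 2 or 3 (0.55, 0.59, 0.48) and pin replicate 2 or 3 (0.54 each). No explanation was tested for these genes.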

How the results depend on the processing

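Total-count and upper-quartile normalization were chosen after seeing the data, and the other alternatives were fixed before. With an absolute log2 fold change of at least 1 required, the genes past the threshold numbered 4082 for pin against Col-0, 3737 for pid, 2744 for mp, 2341 for pid against pin, 1087 for mp against pin, 1934 for mp against pid, 3387 for the mean and 1516 shared by all 3 mutants. In a fit of only the groups compared the count fell in the comparisons with pid, to 6667 from 8952 against Col-0, to 3217 from 5822 against pin and to 2285 from 4415 for mp against pid. It rose in the others, to 10119 from 9506 for pin and 9084 from 7314 for mp against Col-0 and to 2976 from 2303 for mp against pin, and the cause was not tested. With the replicate block the counts were 9540, 8951 and 7377 for pin, pid and mp against Col-0, 5836, 2298 and 4364 between mutants in the same order, 9868 for the mean and 4383 shared. The libraries were not treated as paired: after centring each genotype, 18 same-number pairs correlated at -0.124 to 0.267, 6 of them over 0.1, with a mean of 0.0507 (-0.0256 for different numbers), and the own number fitted best in 6 of 12 libraries, so some pairing is not excluded. DESeq2, RLE, total-count and upper-quartile normalization, both filters and removal of organelle genes left every count of genes within 1.5 times its value. Which direction held more genes against Col-0 was not settled. Total-count normalization turned it in pin, pid, mp, the mean and the shared genes, and the stricter filter in all of these but pid. The fit of only the groups compared turned it in pin (4982 higher and 5137 lower) and mp (4432 and 4652), DESeq2 (4050 and 4100) and RLE (3658 and 3677) in mp, and RLE (4872 and 4955), no filter (4756 and 5062) and the replicate block (4929 and 4939) in the mean. A fold threshold turned it in mp (1235 and 1509), the mean (1687 and 1700) and the shared genes (756 and 760). Of 12 fits without 1 library it turned in 8 for pin (all but those without Col-0 replicate 1 or 3, pid replicate 3 or pin replicate 1), 9 for mp (all but Col-0 replicate 1 or 3 or pin replicate 1), 11 for the mean (all but pin replicate 1), 4 for the shared genes (mp replicate 1, pid replicate 1 or 2, pin replicate 2) and 0 for pid.

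Leaving out 1 library in turn gave 7546 to 10683 genes for pin against Col-0, 6941 to 8969 for pid, 5068 to 8620 for mp, 3648 to 6765 for pid against pin, 1179 to 3170 for mp against pin, 2146 to 5370 for mp against pid, 7292 to 10535 for the mean and 2832 to 4414 shared. Counts moved by over 1.5 times for pid against pin without pin replicate 2 (3648), for mp against pin without mp replicates 1, 2 and 3 (1179, 1295, 1326) and pin replicates 2 and 3 (1286, 1344), and for mp against pid without mp replicates 1 and 2 (2597, 2146). The cause of each shift was not tested. The same runs gave 10 to 12 lists for pin against Col-0, 10 to 12 for pid, 12 to 15 for mp, 11 to 15 for pid against pin, 7 to 9 for mp against pin, 6 to 7 for mp against pid and 10 to 13 for the mean. With an estimated correlation 0 lists passed in every comparison, in place of 11, 10, 13, 12, 7, 6 and 12, and 71 list calls ended. Fry called 17 lists for pin, 16 for pid and 11 for mp against pin. The log2 fold change of LEA7 (AT1G52690), pid vs Col-0, ran from -1.90 without pid replicate 3, a reversed sign, to 7.33 without pid replicate 2, and its cause was not tested. Over all fits without 1 library, 439 of 6888 calls of single named genes ended and 6448 held, and 118 were gained in 3696 cases with no call. With the replicate block 29 of 574 ended and 21 were gained in 308, with only the groups compared 58 of 553 and 24 in 216, and with DESeq2 2 of 558 and 40 in 294.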

Other observations

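Of the tests below, those on chromosome 2, on another accession, on the second abscisic acid list and on the mutant-to-mutant parts of the starvation pattern were chosen only after the result was seen. Loci counted in every Col-0 library at 1 CPM or more and under 0.1 CPM in every mutant library numbered 13, and the ones named here were chosen after their values were seen. Among them were SUP (AT3G23130) at 3.09 ± 0.737 CPM in Col-0, RBE (AT5G06070) at 1.38 ± 0.273, WOX1 (AT3G18010) at 4.60 ± 0.478, NGA2 (AT3G61970) at 4.06 ± 0.415 and NGA4 (AT4G01500) at 1.56 ± 0.138, which are transcription factor genes of flowers and lateral organs. The same criterion gave 29 loci in pid, 1 in pin, AT1G06830 at 4.44 ± 1.49 CPM, and 0 in mp.

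Genes induced by darkness and sugar starvation, SEN1 and ASN1 among them, were lower in pin than in Col-0, and a separate list of 19 tested starvation markers had a median log2 fold change of -2.05 in the mean of the mutants, with 17 lower and 0 higher. The medians were -2.39 in pin, -1.01 in pid and -1.96 in mp, and with an estimated correlation the list had p = 0.13 in the mean. A candidate explanation is a carbon-starvation response in Col-0, from dissection or flower primordia, but a fold change cannot show which side changed. The highest median, -1.01, leaves these open, as handling and primordia go with genotype. Between mutants, all of them touched, the medians were 0.40 for mp against pin and 1.1 (95% bootstrap interval over the markers 0.42 to 2.27) for pid against pin, or 0.60 (0.15 to 1.40) without pid replicate 3, so it stays open whether a difference of Col-0 from pins as such could cover all of it.

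Of 29 loci at the floor in Col-0, pin and mp and counted in every pid library, 5 (17.2%, exact 95% interval 5.85 to 35.8) lay on chromosome 2, which carries PID, against 15.1% of tested genes, and 5 chromosomes held such loci, which argues against a linked segment as the whole cause. Only 1 locus, AT3G29120, was at the floor only in pid, but a loss had to show against 9 libraries and Col-0, pin and mp had 1, 1 and 0, so the genome of another accession stays open. Pseudogenes made up 20.7% of the 29 loci and 35.1% of 10443 loci at the floor in the other libraries. The ratio of 0.589 (two-sided Fisher exact p = 0.12) shows no excess but leaves a release of silent loci open. Whether loci annotated as pseudogenes include transposable element genes is not given in the sources used here, so a release of such genes stays open. A biological effect of the pid mutation stays open and was not tested.

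In pid replicate 3, RAB18 was at 3201 CPM, far above the other pid libraries. Mature seed tissue is unlikely, since seed markers came to 0.0724% of RAB18 there (2.32 CPM in sum). A second abscisic acid list had 12 members outside the list of the report, and none was left out for its counts. Their median log2 ratio of pid replicate 3 to the mean of the other 2 was 3.42 (95% bootstrap interval 1.56 to 4.94, with 0.1 CPM added to each value), while the highest such median of another library was 0.45. Several members were near 0 CPM in the other libraries, so the ratio depends on the value added. The abscisic acid list of the report had a median log2 ratio of 0.80 there, with 16 of 24 members higher. An abscisic acid response in that library may explain it, and what would have set it off was not tested, as the pool is 1 of 3 from the same genotype.

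Other splits of the libraries were counted for each comparison. For the mean of the mutants only the real split of 100 gave 9816 genes (highest other 2624), and for shared genes 4234 (529). Random splits mix genotypes, so neither count tests sharing or mutants against Col-0. For the lists of the mean, 7 of 100 splits gave at least the real 12, the highest other 14, so chance was not excluded. For 3 against 3 libraries 10 splits are too few for a share under 0.05. In fits of 6 libraries the real split and the highest other gave 10119 and 0 genes for pin against Col-0, 6667 and 0 for pid, 9084 and 0 for mp, 3217 and 0 for pid against pin, 2976 and 0 for mp against pin, and 2285 and 0 for mp against pid. For lists they gave 11 and 11 (2 splits as high), 11 and 14 (3), 10 and 10 (2), 13 and 12 (1), 10 and 10 (2) and 6 and 11 (5) in the same order.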
